A study of Mus musculus with 39 samples.

How the data were processed

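RNA from 39 lymphomas of Eµ-myc transgenic mice was profiled on 1 array each. Per the labels, mice with signs of lymphoma or illness were killed, the tumour was frozen, tissue was broken up by grinding and sonication, and RNA was isolated with a silica column kit. Complementary DNA was primed with T7 oligonucleotides and transcribed into biotin-labelled RNA. The labels put all tumours in 1 group, with no control, treatment or outcome, and give no batch or date. The deposited values are log2 expression levels per probe set made by the authors with RMA in the affy package, per the submitters' processing notes. RMA corrects background, quantile normalizes across arrays and summarises probes per probe set. The package version, the number of arrays normalized together and any filter are not given in the sources used here. The log2 scale was read from the values, and no filter on dim probe sets was seen. Quantile normalization gives all arrays nearly the same distribution, so a change in total RNA per cell cannot be seen, and dim genes are compressed toward the background.

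The platform annotation listed 35890 probe sets, of which 34958 named 1 gene and 932 several. A further 9211 were not listed and are unnamed here, 64 of all probe sets were controls. Of the 1-gene probe sets 34754 matched a gene by Entrez identifier in a gene table of the assembly GRCm38.p6, and 0 symbols changed. The chromosome of a gene and the order of genes along it come from that table, and no coordinates are printed. Each of 18194 genes was represented by the probe set with the highest mean, 9012 genes had several, and the lowest correlation between them was recorded. Probe sets were called disagreeing where that r was under about 0.2. No probe set's level was set against another's, and no column of the value table was left unused. The number of arrays limits the precision.

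The gene lists, relations, tests and alternatives were chosen before the data were examined, except where stated. They hold 27 gene lists with 388 entries, of which 352 were measured and the others were not analysed here. The lists cover precursor, mature, pan, germinal centre and plasma B cells, MHC class II, T cells, cytotoxic and NK cells, macrophages, neutrophils, erythroid cells, dendritic cells, fibroblasts, endothelium and adipocytes. They also cover p53 targets, G2/M proliferation, S phase and E2F targets, Myc targets and ribosome biogenesis, interferon response, NF-kB targets, the BCL2 family, hypoxia and glycolysis, immediate early and heat shock genes, Myc network and lesion genes, immunoglobulin constant chains (2 measured, given as genes) and sex-linked genes. A list score is the mean over members of the log2 level minus the gene's mean. Each list's median SD and mean r between members were ranked among 10000 random lists of the same size matched on mean level in 20 bins.

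Relations between scores were computed as Pearson's r and Spearman's rho with 2-sided permutation tests of 100000 draws and Benjamini-Hochberg adjustment over 25 pairs. A further planned pair needed a gene not analysed here. Where an equal-variance mixture model (mclust) with 2 components gained over 10 in BIC with at least 3 tumours in the smaller part, r was computed within the cluster of at least 6 tumours, and the relation was also computed without the 2 tumours farthest from the median. The same rule on the first principal component of the hybridisation controls found no separate cluster of arrays (BIC gain -7.32), so no relation was split by batch, but a batch that these controls do not show is not excluded.

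For each of 4 scores (precursor minus mature B cell score, p53 targets, G2/M proliferation and the Cdkn2a level) every gene was fitted with limma (lmFit and eBayes with trend) on the score divided by its SD. Slopes are in log2 per SD, tests were 2-sided and the threshold was an adjusted p of 0.05. Genes of a score were left out of its fit and lists. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and members were also adjusted over the list alone. No tumour was put into a group. A slope along a score is an association across tumours, and genes share the composition of the tissue with the score.

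Named genes follow a fixed rule: the 25 genes with the largest SD, the 3 members of each list with the largest SD (a selection of these is printed), and all measured Myc network, lesion, immunoglobulin constant chain and sex-linked genes. In each fit they are the 12 largest positive and 12 largest negative slopes among called genes and the 4 largest slopes of each called list. Riken clones, predicted genes and unnamed transcripts were passed over. Genes outside it are said to have been chosen after their values were seen.

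The fits were tested on simulated data with 18194 genes of which 200 followed the score. At slopes of 0.25, 0.5 and 1 log2 per SD, 67.2%, 94.0% and 100% were recovered along the stage score and 59.7%, 85.1% and 98.5% along the p53 target score. For the G2/M score these were 65.7%, 85.1% and 98.5%, and for Cdkn2a 62.7%, 83.6% and 98.5%. Of called genes 4.4%, 5.81%, 6.22% and 5.78% had not been changed, and 0 unchanged lists were called. The simulated genes varied independently of each other and the lists were drawn at random. Genes of the real arrays move together, and a random pairing of the G2/M score with the tumours called up to 3430 genes. These rates of false calls therefore do not carry over to the real fits and list tests. Unrelated pairs gave a p under 0.05 in 6% of cases and pairs made with r 0.6 in 99.5%. The mixture rule split 0% of single normal sets and 88% of sets placed 5 SD apart.

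Alternatives were the mean of all probe sets, only genes above the median level, quantile normalization again, median centring, leaving out the 3 arrays least like the others, other-cell scores or array quality as covariates, Spearman correlation per gene, an adjusted p of 0.01, the median absolute deviation and a score's cluster as a block. Further alternatives were added after the data were seen. R 4.3.3, limma 3.58.1, mclust 6.1.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.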

Results

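RNA from 39 lymphomas of Eµ-myc mice was measured on short-oligonucleotide arrays, 1 array per tumour, and 18194 genes were analysed. The Eµ-myc transgene places Myc under the enhancer of the immunoglobulin heavy chain gene, and carriers develop lymphomas of B lineage cells. The labels put every tumour in 1 group and give no normal tissue, treatment or other contrast; the series is described as a training set. The questions asked were therefore how far transcript levels differed from tumour to tumour, which gene groups moved together, and which genes followed B cell stage, p53 targets, proliferation and Cdkn2a. The labels do not state that each tumour came from a separate mouse, so p-values measure only the spread between these samples. The 39 arrays had medians between 5.61 and 5.78 (log2) and pairs of arrays correlated across probe sets with r between 0.889 and 0.991, so that no pair held identical values. The mean r with the other arrays was lowest in tumour 6 (0.912), tumour 8 (0.916) and tumour 2 (0.918). The 3' minus 5' difference of the actin and Gapdh control probe sets ran from -0.00078 to 0.395 (log2), and the mean of the poly-A controls from 6.70 in tumour 39 to 9.66, with a median of 9.24. The mean of the hybridisation controls ran from 10.49 to 11.22. Their first principal component did not separate the arrays into clusters (BIC gain -7.32), which does not exclude a batch, and the labels name none. Tumours are named by the numbers in the labels.

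Bpifa2, a salivary protein gene, had the largest spread, with a mean of 6.48 ± 4.48 (log2, SD, n = 39) and levels from 3.32 to 14.84. Pou2af1, a transcriptional coactivator of B cells, averaged 11.39 ± 3.05 and fell to 3.10 in tumour 6. Cdkn2a, which encodes the tumour suppressors Arf and p16Ink4a, averaged 8.30 ± 2.55 and ran from 4.14 in tumour 6 to 12.17 in tumour 9. Myc itself averaged 11.73 ± 0.77, with 12.63 in tumour 10 and 8.19 in tumour 2. Of 18194 genes, 1333 (7.33%) had an SD of at least 1 and 5033 (27.7%) an SD of at least 0.5.

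Among the 25 genes with the largest SD, the secretory genes Amy1 (SD 3.87), Pip (3.73), Car6 (3.67), Smr3a (3.49), Cst10 (3.47), Dnase1 (3.33), Chia1 (3.23), Scgb2b27 (2.84) and Wfdc12 (2.68) were highest in tumour 25, the tumour with the highest Bpifa2. Dcpp3 (SD 2.85) and A2ml1 (SD 2.68) were highest in tumour 7. Ly6k (SD 3.01) and Cd8b1 (SD 2.66), a chain of the CD8 coreceptor, were highest in tumour 32. Reln had an SD of 2.83 and the potassium channel gene Kcnk1 an SD of 2.68. Ms4a1, which encodes the B cell surface protein CD20, ran from 4.17 in tumour 8 to 13.67 in tumour 18. A kappa variable gene (SD 2.67) and the lambda variable gene Iglv1 (SD 2.58), both of immunoglobulin light chains, were also among the 25, and the probe sets of Iglv1 disagreed (r = 0.099). Rgs13, a germinal centre gene, ran from 2.58 to 12.31, with its highest level in tumour 18. The sex-linked genes Xist (SD 3.88), Eif2s3y (3.43) and Kdm5d (2.63) were also among the 25, and Uty had an SD of 1.19.

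**Figure D1:**
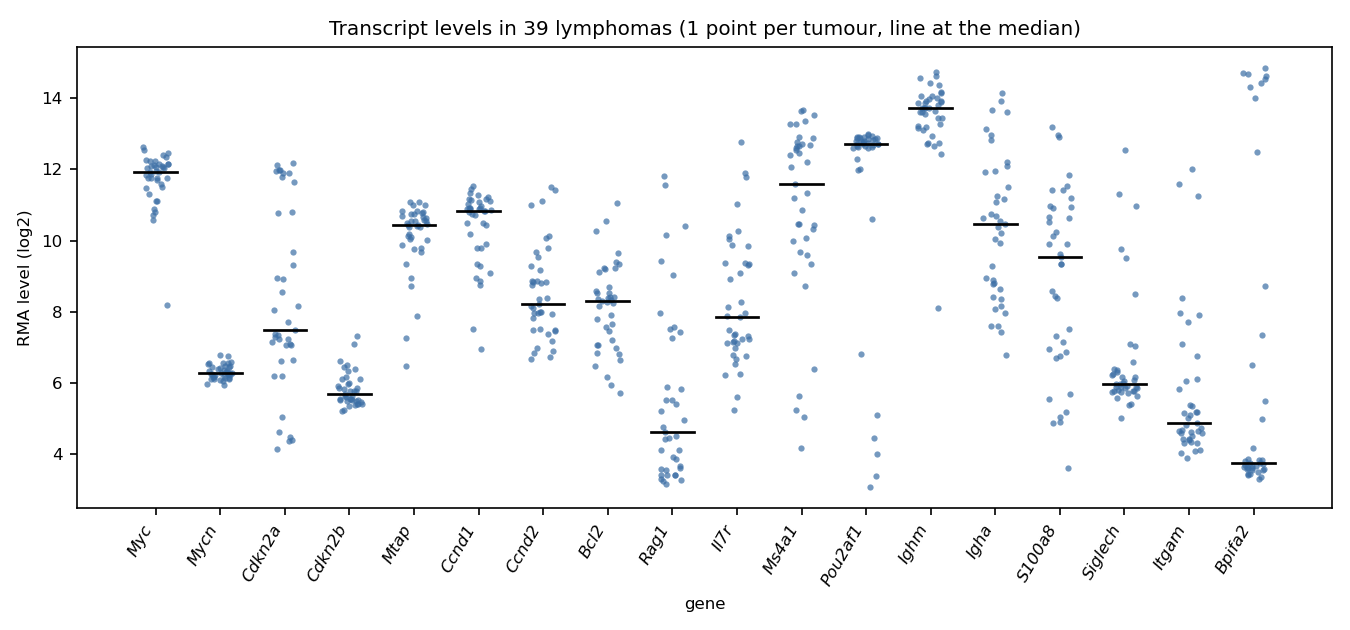
Level of 18 genes in the 39 lymphomas, on the log2 scale of the deposited values; each point is a tumour and each line a median. Myc is lowest in tumour 2 (8.19), Cdkn2a spreads from 4.14 to 12.17, and Pou2af1 falls to 3.10 and Bpifa2 rises to 14.84 in single tumours.

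Among the Myc network and lesion genes Cdkn2a varied most (SD 2.55), followed by Ccnd2, Ccnd1 and Mtap. Ccnd2 averaged 8.55 ± 1.31 with its highest level in tumour 2, and Ccnd1 averaged 10.37 ± 1.06 with its lowest in tumour 21 (6.95). Mtap, the neighbour of the Cdkn2a locus, averaged 10.11 ± 1.02, and tumours 13 (6.49), 1 (7.25) and 7 (7.89) formed a separate low cluster. Other members had SDs of 0.87 for Ccnd3, 0.68 for Pim1, 0.66 for Bmi1, 0.55 for Bcl2l11, 0.54 for Mxi1, 0.49 for E2f3, 0.48 for Rb1 and for Cdkn2b, and 0.46 for Cdkn1b. Mxd1 (0.43), Mdm4 (0.39), Max (0.32), Nras (0.31), Mnt (0.25), Mycn (0.20), Mycl (0.20) and E2f4 (0.17) varied least. The probe sets of Mycn, Mycl, Mnt, Mxd1, Mdm4, Ccnd3 and Rb1 disagreed, with a lowest r of 0.14 for Mnt and less for the others. Of the immunoglobulin constant chains, Ighm averaged 13.50 ± 1.05 and was at 8.11 in tumour 18 against 12.43 in the next lowest tumour, but its probe sets disagreed (r = -0.23). Igha averaged 10.38 ± 2.04 and was highest in tumour 1 (14.13).

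The gene lists for B cell stages and for cells other than B cells varied more than random lists of matched size and level. The median SD of a member was 1.37 for mature B cell genes, 1.34 for precursor B cell genes, 1.16 for pan B cell genes, 1.23 for MHC class II, 1.39 for germinal centre genes and 1.31 for plasma cell genes. Rag1, which cuts immunoglobulin genes in precursor cells, ran from 3.18 to 11.81 in tumour 29, and the cytokine receptor gene Il7r reached 12.77 in tumour 21. Neutrophil genes had a median SD of 1.52, with S100a8 from 3.61 in tumour 8 to 13.18 in tumour 7. T cell (1.16), cytotoxic and NK cell (1.11), dendritic cell (1.01), adipocyte (1.00), macrophage (0.92) and fibroblast genes (0.90) followed, and each of these lists lay above at least 99.76% of the random lists. The sex-linked list had a median SD of 3.03. The erythroid list (0.25) lay above 57.8% and the endothelium list (0.49) above 72.1% of the random lists, so neither varied more than matched genes do. Among the pathway lists, interferon response (1.04), immediate early and heat shock (0.72), NF-kB targets (0.70), G2/M proliferation (0.66), hypoxia and glycolysis (0.64), S phase and E2F targets (0.59), p53 targets (0.58) and Myc targets and ribosome biogenesis (0.43) each lay above at least 98.8%. The excess of the Myc targets and S phase genes rested on a few tumours: they lay above 32.9% and 90.25% of random lists without tumours 2, 6 and 8, and above 18.8% and 88.1% without the 7 tumours with a pan B cell score under -1 or a Myc level under 10. Leaving out the 7 also lowered the median SD to 0.50 for pan B cell, 0.87 for plasma cell, 0.58 for dendritic cell, 0.65 for adipocyte and 0.34 for G2/M genes, which still lay above at least 97.38% of random lists. Most of the 7 were picked by a low pan B cell score, so the drop for that list was largely set beforehand. After regression on the T cell, macrophage, erythroid and fibroblast scores the median SD was 0.77 for MHC class II, 0.57 for cytotoxic, 0.58 for dendritic cell, 0.40 for S phase and 0.46 for NF-kB genes (above 94.65%). The mean of all probe sets gave 0.85 for precursor B cell and 1.51 for sex-linked genes, and genes above the median level gave 1.75 for dendritic cells. The Myc network and lesion genes (0.49) lay above 96.05% and the BCL2 family (0.55) above 90.55%.

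Members of most lists moved together from tumour to tumour. The mean r between members was 0.86 for G2/M proliferation, 0.85 for MHC class II, 0.78 for Myc targets, 0.77 for adipocyte genes and 0.73 for S phase genes. It was 0.68 for cytotoxic and for neutrophil genes, 0.65 for germinal centre genes, 0.61 for NF-kB targets, 0.60 for T cell and for interferon genes, 0.48 for mature B cell genes and 0.34 for pan B cell genes. For Myc targets it was 0.46 without tumours 2, 6 and 8 and 0.41 without the 7 tumours, where it was 0.47 for S phase and 0.21 for pan B cell genes. The drop for pan B cell genes was again largely set by how the 7 were picked. After regression on the other-cell scores the mean r was 0.39 for cytotoxic and 0.41 for NF-kB genes. The p53 targets moved together only weakly (0.15, above 99.89% of random lists). The BCL2 family did not (-0.03, above 16.5%), nor did the Myc network and lesion genes (0.00478, above 39.5%) or the sex-linked genes (0.06, above 66.3%). The sex-linked list joins Xist with the Y-linked genes Eif2s3y, Kdm5d and Uty. Its mean r therefore does not show whether the Y-linked genes moved together. Percentiles describe these arrays and are no test across samples.

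A few tumours stood apart in many lists. Tumour 2 had the highest scores for mature B cell (2.71), MHC class II (2.62), plasma cell (1.81), T cell (2.95), cytotoxic (3.41), dendritic cell (1.82), interferon (3.02) and NF-kB genes (2.35), also the highest for macrophage genes, and the lowest for G2/M (-2.46), S phase (-1.82) and Myc targets (-1.84). The pan B cell score put tumours 5, 6, 8, 19, 23 and 26 in a separate low cluster. In tumours 6, 8 and 23 the macrophage genes Itgam (11.26, 12.01 and 11.58) and Adgre1 (13.05, 13.12 and 12.55) were the highest of all tumours. These genes are only part of the macrophage list of 20. By the score of the whole list tumours 6 (1.229) and 23 (1.015) followed tumour 2. Tumour 8 (0.68), however, lay below tumours 22 (0.87) and 1 (0.76). The neutrophil scores of tumours 6, 8 and 23 were negative (-0.40, -1.70 and -1.01). Siglech, a gene of plasmacytoid dendritic cells, was at 12.54 in tumour 32, 11.30 in tumour 5 and 10.96 in tumour 19, and averaged 6.67 ± 1.75. Adipoq, an adipocyte gene, reached 12.55 in tumour 6. Germinal centre genes were highest in tumour 18 (score 4.84), where Gcsam was at 10.37 against a mean of 3.84 over all tumours. The hypoxia score separated tumours 6, 8 and 23, the immediate early score tumours 2, 6, 8, 18 and 23, the cytotoxic score tumours 1, 2, 18 and 27, and the dendritic score tumours 2, 5, 6, 19, 22, 26, 27 and 32.

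**Figure D2:**
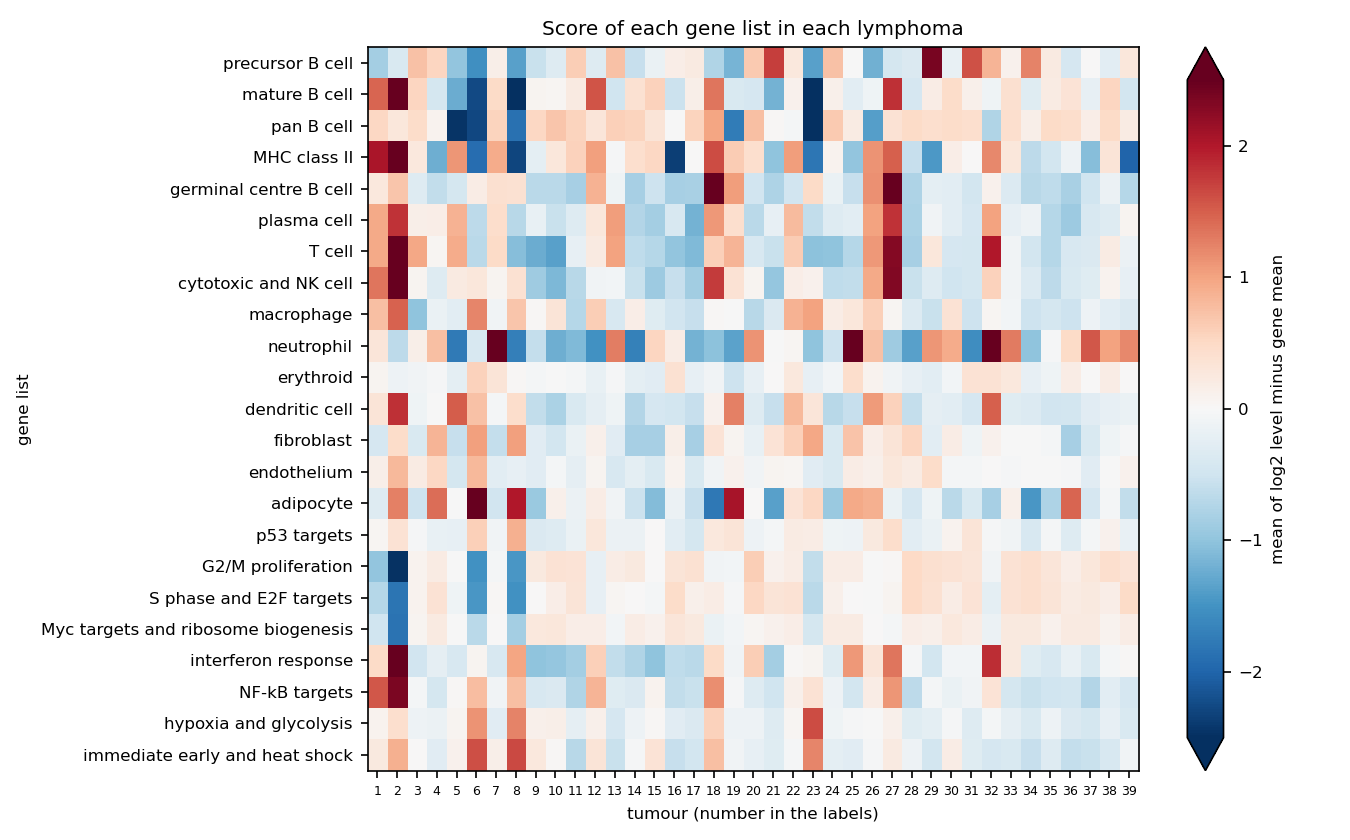
Score of 23 gene lists (vertical axis) in each of the 39 lymphomas (horizontal axis), as the mean over members of the log2 level minus the gene mean. Tumours 5, 6, 8, 19, 23 and 26 are low for pan B cell genes, and tumour 2 is high for T cell and cytotoxic genes and low for G2/M genes.

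Myc transcript and its target genes rose and fell together. The Myc level correlated with the score of 22 Myc target and ribosome biogenesis genes with r = 0.926 (rho = 0.726, permutation p = 1e-05 for each, adjusted p = 6.2e-05, n = 39), and with r = 0.793 without tumours 2 and 8. S phase genes moved with G2/M genes (r = 0.846, rho = 0.746, adjusted p = 6.2e-05) and Myc targets with G2/M genes (r = 0.740, rho = 0.575, adjusted p = 6.2e-05), over the 35 tumours left when the separate low G2/M cluster of tumours 1, 2, 6 and 8 was set aside. T cell genes moved with cytotoxic genes in 35 tumours (r = 0.698, rho = 0.638, adjusted p = 6.2e-05). Higher p53 target scores went with lower G2/M scores in 35 tumours (r = -0.523, rho = -0.537, p = 0.0011, adjusted p = 0.003, and r = -0.581 without tumours 27 and 31).

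Of 26 planned relations 25 were computed, 12 of them within a cluster, and 16 had an adjusted p under 0.05 for r, 12 positive and 4 negative. T cell and interferon scores moved together (r = 0.632, rho = 0.392, p = 8e-05, adjusted p = 4e-04, and r = 0.390 without tumours 2 and 27). Macrophage scores rose with interferon (r = 0.526, rho = 0.508, p = 0.00072, adjusted p = 0.0026) and with fibroblast scores (r = 0.518, rho = 0.449, p = 0.00076, adjusted p = 0.0026), and r was 0.390 and 0.433 without tumours 2 and 6. G2/M scores were lower where macrophage (r = -0.547, rho = -0.479, p = 0.00083, adjusted p = 0.0026), hypoxia (r = -0.481, rho = -0.447, p = 0.0036, adjusted p = 0.0082, n = 34) and germinal centre scores (r = -0.473, rho = -0.548, p = 0.011, adjusted p = 0.019) were higher. Without the tumours farthest from the median these were -0.352, -0.417 and -0.644. Given the T cell, macrophage, erythroid and fibroblast scores, the partial r with G2/M genes was -0.186 for p53 targets (adjusted p = 0.39), -0.316 for hypoxia (0.16) and -0.196 for germinal centre genes (0.37), so that none of the 3 passed. Without the 7 tumours G2/M with macrophage scores (r = -0.377, adjusted p = 0.06), macrophage with interferon (0.334, 0.097) and fibroblast scores (0.236, 0.24) and precursor B cell with G2/M genes (0.197, 0.34) did not pass either. Precursor B cell genes rose with G2/M genes (r = 0.454, rho = 0.359, p = 0.0071, adjusted p = 0.014), but rho did not pass (adjusted p = 0.063). Myc rose with Mycn (r = 0.441, rho = 0.425, p = 0.0049, adjusted p = 0.01), but r was 0.0219 (adjusted p = 0.93) with the mean of all probe sets of a gene, and the Mycn probe sets disagreed. For Myc with S phase genes (r = 0.441, rho = 0.281, p = 0.0079, adjusted p = 0.014, n = 36), mature B cell with plasma cell genes (r = 0.464, rho = 0.212, p = 0.0031, adjusted p = 0.0077) and mature B cell genes with NF-kB targets (r = 0.378, rho = 0.283, p = 0.019, adjusted p = 0.03) r passed and rho did not (adjusted p = 0.15, 0.26 and 0.14). Without the farthest tumours r was 0.360, 0.332 and 0.261. Mature B cell genes with NF-kB targets gave, without the 7 tumours, r = 0.796 (adjusted p = 8.3e-05) and rho = 0.597 (adjusted p = 0.0034), while there Myc with S phase genes (r = 0.287, adjusted p = 0.16) and Myc with Mycn (r = 0.245, adjusted p = 0.23) did not pass. The smallest p that the permutations can give is 1e-05.

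The other 9 relations did not pass. The adjusted p was 0.46 for precursor with mature B cell genes (r = 0.137, rho = -0.0095), 0.48 for precursor B cell genes with MHC class II (r = -0.128, rho = -0.196) and 0.67 for mature B cell genes with p53 targets (r = -0.0703, rho = 0.239). Without the 7 tumours these became -0.517 (adjusted p = 0.0082), -0.407 (0.041) and 0.606 (0.0014). Cdkn2a with p53 targets (r = -0.142, rho = -0.0093, adjusted p = 0.46), with Cdkn2b (r = 0.172, rho = 0.345, adjusted p = 0.39) and with Mtap (r = -0.149, rho = -0.270, adjusted p = 0.46, n = 36) did not pass. For Cdkn2a with Cdkn2b rho was 0.447 (adjusted p = 0.021) without tumours 2, 6 and 8 and 0.594 (adjusted p = 0.0034) without the 7 tumours, where r was 0.380 (adjusted p = 0.052). T cell with macrophage scores gave r = 0.199 (rho = 0.0557, adjusted p = 0.31), and pan B cell scores gave r = -0.272 with T cell (rho = -0.184, adjusted p = 0.18) and r = -0.124 with macrophage scores (rho = -0.0836, adjusted p = 0.5) in 33 tumours.

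**Figure D3:**
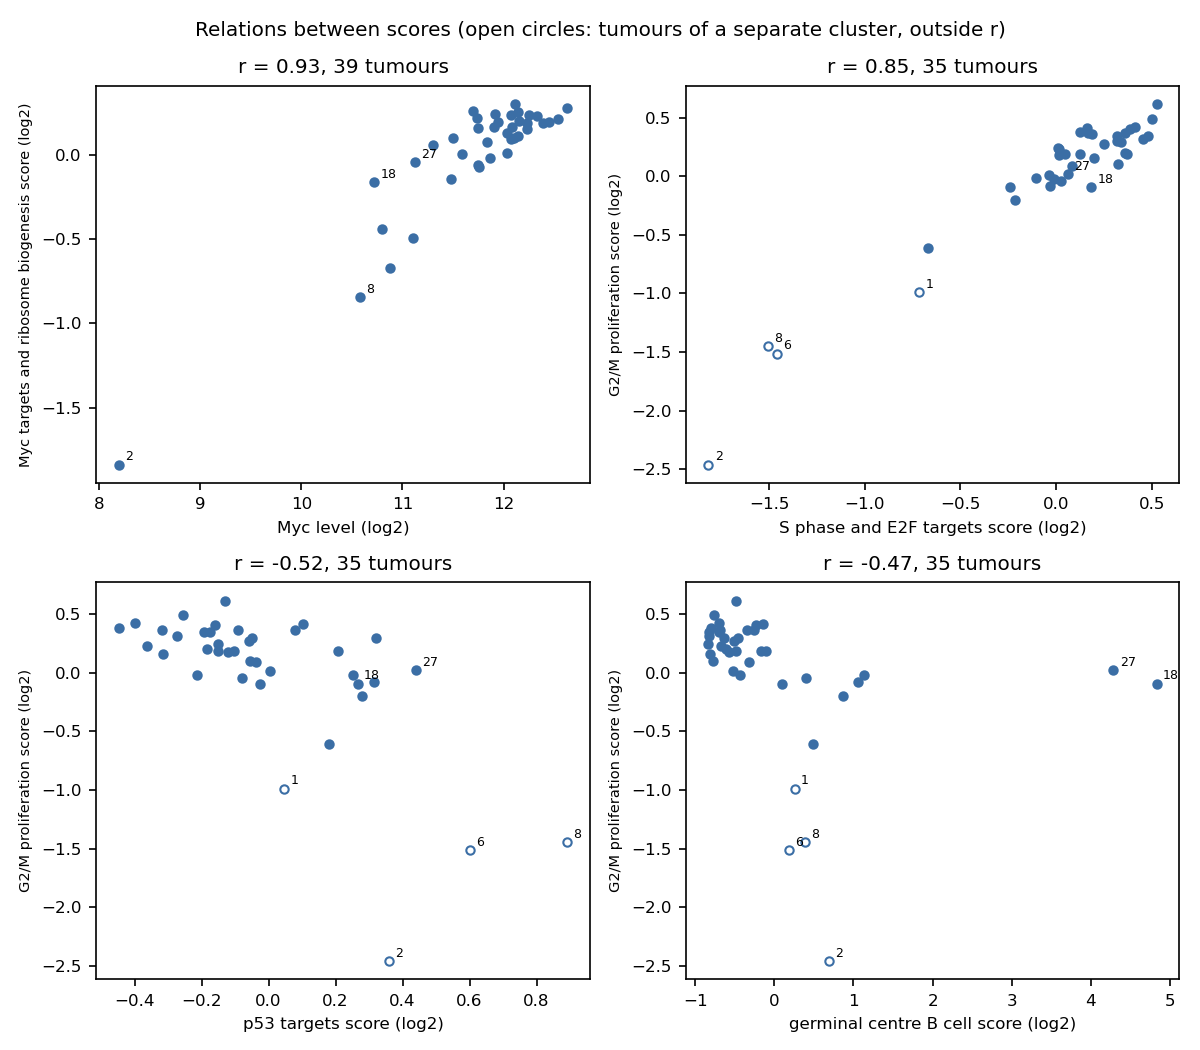
Score or level on each axis in log2 units, 1 point per tumour, with open circles for tumours of a separate cluster that stay outside r. Myc rises with its targets (r = 0.926) and S phase with G2/M genes (r = 0.846), and p53 targets (r = -0.523) and germinal centre genes (r = -0.473) go against G2/M genes.

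Along the B cell stage score, the precursor minus the mature B cell score, the genes of antigen presentation by MHC class II fell, as did a pair of chemokine genes. Over all tumours its parts did not oppose each other (r = 0.137). Tumours 6, 8 and 23 had low precursor scores (-1.531, -1.355 and -1.357) but lower mature scores (-2.247, -2.505 and -2.516). They thus lie on its precursor side, with MHC class II scores of -1.91, -2.30 and -1.81, though poor in B cell transcripts. Without the 7 tumours that stood apart, these included, the list still fell by camera (adjusted p = 1.9e-11 at the preset correlation). Fcmr, the Fc receptor for IgM, fell by 1.60 ± 0.30 (log2 per SD of the score, SE, n = 39) with a limma adjusted p of 0.0013. P2ry10, a lysophospholipid receptor gene of lymphocytes, fell by 1.41 ± 0.23, the chemokine genes Cxcl13 by 1.31 ± 0.29 and Cxcl9 by 1.29 ± 0.29 (without the 7 tumours that stood apart adjusted p = 0.055). Among the genes that rose were Mei4 (0.90 ± 0.28, adjusted p = 0.045), a gene of meiotic recombination, Insm1 (0.88 ± 0.25), a transcription factor gene, and Slco4a1 (0.74 ± 0.13, adjusted p = 0.00073), a transporter gene. In all, 506 genes rose and 574 fell of 18168 tested. With each array centred on its median 1086 rose and 555 fell, so that 66.2% of the called genes rose in place of 46.9%.

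Further genes that rose were Ptgr1 (0.84), Sertad4 (0.83), Hacd1 (0.77), Aplnr (0.76), Capsl (0.70), Tifa (0.70), Dleu7 (0.67), Gpat3 (0.66) and Elovl6 (0.65). Further genes that fell were Iglv1 (-1.45, with probe sets that disagreed), Ubd (-1.27), Rab30 (-1.17), Bend5 (-1.17), Gimap4 (-1.17), H2-DMb2 (-1.16), Clec4e (-1.14) and Bcar3 (-1.13, with probe sets that disagreed). All 9 measured MHC class II genes fell, led by H2-DMb2, H2-DMa (-0.94 ± 0.16), H2-Oa (-0.92) and the invariant chain gene Cd74 (-0.90), and the list fell by camera (adjusted p = 2.7e-19 at the preset correlation and 0.019 with an estimated correlation). Of 14 cytotoxic and NK cell genes 10 fell and 4 did not pass (12 fell when adjusted over the list alone), with the transcription factor gene Tbx21 at -0.93, Nkg7 at -0.86 and Ifng at -0.81, and 8 of 14 NF-kB targets fell (13 adjusted over the list alone), with Traf1 at -0.69, Nfkbie at -0.65 and Tnfaip3 at -0.62. Both calls held with an estimated correlation (adjusted p = 0.037 for each). These were the 3 list calls along the stage score that did.

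The fall of the other lists was called only at the preset correlation. Of the germinal centre genes Fas (-0.72), Mef2b (-0.72) and Gcsam (-0.70) fell of 7 (6 adjusted over the list alone), with adjusted p = 0.078 with an estimated correlation. Of the T cell genes 6 fell of 14 (7 adjusted over the list alone), with Cd3g at -1.07 and Cd3d at -0.81 (adjusted p = 0.094 with an estimated correlation). The macrophage genes Cd5l (-0.88), Msr1 (-0.47) and C1qa (-0.39) fell of 20 (5 adjusted over the list alone; adjusted p = 0.093 with an estimated correlation), and Ell2 (-0.92), with probe sets that disagreed, fell of the 10 plasma cell genes (3 adjusted over the list alone; adjusted p = 0.094 with an estimated correlation). The apoptosis inhibitor genes Bcl2 (-0.79 ± 0.15) and Mcl1 (-0.18) fell of the 11 BCL2 family genes (3 adjusted over the list alone; adjusted p = 0.081 with an estimated correlation). Interferon response had falls of Gbp2 (-0.99), Gbp3 (-0.69) and Zbp1 (-0.63) of 18 (3 adjusted over the list alone; adjusted p = 0.19 with an estimated correlation), and pan B cell genes of Blk (-0.79) and Ikzf3 (-0.68) of 12 (3 adjusted over the list alone; adjusted p = 0.38 with an estimated correlation). Jund (-0.17), with probe sets that disagreed, fell of 13 immediate early genes (1 adjusted over the list alone; adjusted p = 0.25 with an estimated correlation). No dendritic cell gene of 8 (2 adjusted over the list alone) and no p53 target of 20 (0 adjusted over the list alone) fell singly, and the calls of these lists had adjusted p = 0.26 and adjusted p = 0.34 with an estimated correlation. Of 18 G2/M genes the kinase gene Aurka (0.33) and Ccnb2 (0.29) rose (4 adjusted over the list alone), of 20 S phase genes E2f1 (0.23) and Gins2 (0.24) rose, and of 22 Myc targets Cdk4 (0.23) and Npm1 (0.09) rose (2 adjusted over the list alone in each). Their calls had adjusted p = 0.38, adjusted p = 0.42 and adjusted p = 0.42 with an estimated correlation. The calls of pan B cell genes (adjusted p = 0.071), plasma cell genes (0.11), dendritic cell genes (0.34) and p53 targets (0.071) ended without the 7 tumours at the preset correlation, and hypoxia genes were called downward (0.0013). With other-cell scores as covariates the calls of plasma cell (0.87), T cell (0.25), macrophage (0.45), immediate early (0.41), BCL2 family (0.16) and p53 target genes (0.72) ended. There the G2/M (0.34), S phase (0.16) and Myc target lists (0.16) turned downward and the dendritic list upward (0.23), none of them called. The T cell and macrophage scores were themselves covariates, which removes the mean slope of their members. The end of those list calls was therefore fixed in advance. C1qa, Jund, E2f1, Gins2 and Npm1 were chosen after their values were seen. Among the lesion genes Ccnd2 (-0.84 ± 0.16) and Cdkn2b (-0.25) fell, and Cdkn2a was at -0.57 ± 0.40 (adjusted p = 0.42). T cell, cytotoxic and macrophage transcripts fell beside the MHC class II genes, and with the T cell, macrophage, erythroid and fibroblast scores as covariates 20 genes rose and 27 fell. By Spearman correlation per gene 55 rose and 82 fell, and without tumours 2, 6 and 8, the 3 arrays least like the others, 215 rose and 294 fell.

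Along the p53 target score, proliferation genes fell and NF-kB target, cytotoxic and macrophage genes rose by camera at the preset correlation, and each of these lists had adjusted p = 0.25 with an estimated correlation. Pou2af1 fell by 1.70 ± 0.40 (log2 per SD, SE, n = 39, limma adjusted p = 0.001), Reln by 1.70 ± 0.36 and Vpreb3, a gene of B cell precursors, by 1.38 ± 0.29. Fpr2, a receptor for formylated peptides on myeloid cells, rose by 1.57 ± 0.22 (adjusted p = 2e-06), the cytokine subunit gene Ebi3 by 1.47 ± 0.23, Ltb, which encodes lymphotoxin beta, by 1.45 ± 0.24, and the integrin gene Itgam by 1.37 ± 0.25. Myc fell by 0.46 ± 0.10 (adjusted p = 0.00042). Of 18174 genes tested 3138 rose and 2965 fell. The highest p53 target scores were those of tumour 8 (0.89) and tumour 6 (0.60), tumours with high Itgam and Adgre1, and without the 7 tumours that stood apart 894 rose and 408 fell. The calls of Pou2af1 (-0.06, adjusted p = 0.64), Reln, Vpreb3, Ebi3, Itgam, Gfi1, Egfl6, Akap12, Tnfrsf19, Trib2, Kcnk1 and Gpr31b ended without them, and with other-cell scores as covariates 125 genes rose and 38 fell. Pou2af1 is a member of the pan B cell score by which most of the 7 tumours were picked, so the end of its call was largely set beforehand.

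Further genes that rose were St8sia6 (1.53), Cdk14 (1.47), Ehf (1.42), Btbd11 (1.39), Nfkbiz (1.36), Lst1 (1.35), Batf3 (1.34) and Gpr31b (1.34). Further genes that fell were Foxf2 (-1.49, with probe sets that disagreed), Gfi1 (-1.34), Egfl6 (-1.27), Akap12 (-1.23), Fcrla (-1.21), Tnfrsf19 (-1.17), Lrrn4 (-1.16), Trib2 (-1.16, with probe sets that disagreed) and Kcnk1 (-1.15). No list call along this score held with an estimated correlation. Of 18 G2/M genes 17 fell (17 adjusted over the list alone), with Kif11 at -0.53 ± 0.08 and Ccna2 at -0.53, of 20 S phase genes 18 fell (19 adjusted over the list alone), with E2f2 at -0.65, and of 22 Myc targets 19 fell (20 adjusted over the list alone), with Cad at -0.47. The adjusted p was 1.2e-11, 2.8e-10 and 2.8e-10 at the preset correlation, and adjusted p = 0.25 with an estimated correlation for each. NF-kB targets rose in 9 of 14 (13 adjusted over the list alone), with Cd83 at 1.13, Bcl3 at 1.11 and the inhibitor gene Tnfaip3 at 0.76, and cytotoxic genes in 12 of 14 (14 adjusted over the list alone), with Gzmb at 1.05. Of 20 macrophage genes 12 rose and Mrc1 (-0.36) fell (12 and 1 adjusted over the list alone), with Marco at 0.79 and Adgre1 at 0.74, and of 17 hypoxia genes 11 rose, Ndrg1 by 1.16, and Ldha (-0.12) fell (11 and 2 adjusted over the list alone). The immediate early genes Atf3 (0.97), Fos (0.94) and Jun (0.71) were among 8 of 13 that rose (8 adjusted over the list alone), and 6 of 13 fibroblast genes rose (6 adjusted over the list alone), with Dcn at 0.53. The calls of NF-kB, cytotoxic, macrophage, hypoxia, immediate early and fibroblast genes all had adjusted p = 0.25 with an estimated correlation. Interferon genes rose in 12 of 18 (12 adjusted over the list alone), with Gbp2 at 1.03, and the adipocyte genes Adipoq (0.86), Lpl (0.68), Cidec (0.61), Lep (0.41) and Fabp4 (0.35) rose of 6 (5 adjusted over the list alone). The dendritic cell genes Batf3, Itgax (0.48) and Xcr1 (0.30) rose of 8 (3 adjusted over the list alone), and these lists each had adjusted p = 0.32 with an estimated correlation. The germinal centre genes Bcl6 (1.28), Rgs13 (1.22), Fas (0.59), Mef2b (0.55) and S1pr2 rose of 7 (5 adjusted over the list alone; adjusted p = 0.28 with an estimated correlation). Of 14 T cell genes 6 rose (6 adjusted over the list alone), with Cd28 at 0.76 (adjusted p = 0.52 with an estimated correlation). The precursor B cell genes Myb (-1.15), Bcl7a (-0.88), Sox4 (-0.69, with probe sets that disagreed) and Cd93 (-0.53) fell of 13 (4 adjusted over the list alone; adjusted p = 0.44 with an estimated correlation). Without the 7 tumours the slopes of Adgre1 (-0.18, adjusted p = 0.41), Cidec (-0.059) and Lep (-0.028) turned negative and the adipocyte list turned downward (adjusted p = 0.66), the precursor B cell call ended (0.75) and mature B cell genes (8.5e-07), MHC class II (4e-08) and plasma cell genes (9.7e-05) were called upward at the preset correlation. With other-cell scores as covariates Itgax was at -0.062, the interferon (adjusted p = 0.93), macrophage (0.82) and fibroblast lists (0.39) turned downward, and the calls of these and of T cell (0.96), dendritic cell (0.93) and adipocyte genes (0.24) ended, while neutrophil genes were called downward (0.00059). The macrophage, fibroblast and T cell scores were themselves covariates, which removes the mean slope of their members. The end of those list calls was therefore fixed in advance, and the direction of those lists there carries no meaning. Mrc1, Ldha, Fabp4, S1pr2 and Cd93 were chosen after their values were seen.

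Along the G2/M proliferation score, S phase genes and Myc targets rose, with adjusted p = 0.00039 and adjusted p = 0.0022 with an estimated correlation. NF-kB targets and cytotoxic genes fell by camera at the preset correlation, with adjusted p = 0.095 and adjusted p = 0.29 with an estimated correlation. Vpreb3 rose by 1.75 ± 0.24 (log2 per SD, SE, n = 39, limma adjusted p = 1.1e-07), Bcat1, an enzyme of branched-chain amino acid metabolism, by 1.51 ± 0.11 (adjusted p = 6.8e-15), the transcription factor gene Myb by 1.40 ± 0.15 and Myc by 0.66 ± 0.06 (adjusted p = 6.9e-11). Fpr2 fell by 1.74 ± 0.18 (adjusted p = 2.9e-10), Ebi3 by 1.56 ± 0.22 and Itgam by 1.40 ± 0.24. Of 18176 genes tested 3639 rose and 3723 fell. Tumours 1, 2, 6 and 8 formed the separate low cluster of this score, and with that cluster as a block 1985 rose and 1348 fell.

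Further genes that rose were Reln (1.66), Pou2af1 (1.55), Foxf2 (with probe sets that disagreed), Akap12 (1.37), Egfl6 (1.25), Gfi1 (1.23), Otub2 (1.22), Ptgr1 (1.20) and Myl4 (1.18). Further genes that fell were St8sia6 (-1.66), Cdk14 (-1.44), Ltb (-1.43), Igsf6 (-1.39), Batf3 (-1.38), Ncf1 (-1.37), Cfb (-1.36), Btbd11 (-1.36) and Gpr31b (-1.35). All 20 S phase genes rose, with E2f2 at 0.82 ± 0.10, Ccne2 at 0.81 and Cdc6 at 0.79 (list adjusted p = 3.6e-21 at the preset correlation and 0.00039 with an estimated correlation). All 22 Myc targets rose, with Cad at 0.59, Srm at 0.56 and Polr1b at 0.55 (adjusted p = 1.4e-21 and 0.0022). These 2 calls held with an estimated correlation and the others did not. All 14 NF-kB targets fell, with Cd83 at -1.18 and Bcl3 at -1.12 (adjusted p = 0.095 with an estimated correlation), and all 14 cytotoxic genes fell, with Gzmb at -0.97 (adjusted p = 0.29 with an estimated correlation). Counts in these 4 lists were unaltered when adjusted over the list alone. Of 20 macrophage genes 12 fell (13 adjusted over the list alone), with Adgre1 at -0.95 and Cd14 at -0.81 (adjusted p = 0.17 with an estimated correlation), and of 18 interferon genes 14 fell (15 adjusted over the list alone), with Gbp2 at -1.08 (adjusted p = 0.42 with an estimated correlation). Of 13 immediate early genes 8 fell (9 adjusted over the list alone), with Atf3 at -1.02 and Fos at -0.98 (adjusted p = 0.16 with an estimated correlation). Of 20 p53 targets 7 fell, among them Cdkn1a (-0.62), the cell cycle inhibitor gene, and Phlda3 (-0.40), and the exonuclease gene Aen (0.31) rose (7 and 1 adjusted over the list alone; adjusted p = 0.3 with an estimated correlation). Of 17 hypoxia genes 9 fell, Ndrg1 by 1.29, and Ldha (0.24) rose (10 and 1 adjusted over the list alone; adjusted p = 0.46 with an estimated correlation). The adipocyte genes Adipoq (-0.88), Lpl (-0.74), Cidec (-0.63), Lep (-0.48) and Fabp4 (-0.46) fell of 6 (5 adjusted over the list alone; adjusted p = 0.46 with an estimated correlation). Of 14 T cell genes 6 fell, among them Cd28 (-0.65) and Thy1 (-0.61) (8 adjusted over the list alone; adjusted p = 0.57 with an estimated correlation). The dendritic cell genes Batf3, Itgax (-0.67), Xcr1 (-0.48), Cd209a (-0.22) and Ccl22 fell of 8 (6 adjusted over the list alone; adjusted p = 0.18 with an estimated correlation). Without the 7 tumours that stood apart 2373 genes rose and 1549 fell, and the calls of Itgam (-0.23, adjusted p = 0.36), Reln, Pou2af1, Egfl6 and Gfi1 ended. For Pou2af1, a pan B cell gene, this was largely set beforehand by how the 7 tumours were picked. The slopes of Adipoq (0.019), Lpl (0.083), Cidec (0.019) and Lep (0.016) turned positive without them, and the adipocyte list turned upward (adjusted p = 0.74). At the preset correlation the calls of p53 targets (0.14) and hypoxia genes (0.31) also ended, and mature B cell genes (0.00088), MHC class II (1.5e-05), germinal centre (0.013) and plasma cell genes (0.0078) were called downward. With other-cell scores as covariates the calls of interferon (adjusted p = 0.4), macrophage (0.86), T cell (0.79), hypoxia (0.33), adipocyte (0.26), dendritic cell (0.26) and p53 target genes (0.4) ended. For the macrophage and T cell lists this was fixed in advance, since their own scores were covariates. Aen, Ldha, Fabp4, Cd209a and Ccl22 were chosen after their values were seen.

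Along the Cdkn2a level, single genes of varied functions rose or fell, and no gene list held with an estimated correlation. Pfn2, a profilin gene, rose by 1.27 ± 0.21 (log2 per SD, SE, n = 39, limma adjusted p = 0.0012), the arginase gene Arg1 by 1.19 ± 0.26 (adjusted p = 0.009), the acute phase gene Saa3 by 1.03 ± 0.29 (adjusted p = 0.037) and the Wnt receptor gene Fzd6 by 0.89 ± 0.16 (adjusted p = 0.002). Emb, a cell adhesion gene, fell by 0.96 ± 0.25 (adjusted p = 0.021), the leukotriene receptor gene Cysltr1 by 0.94 ± 0.22 (adjusted p = 0.013) and the glutaredoxin gene Glrx by 0.61 ± 0.10 (adjusted p = 0.0012). Of 18193 genes tested 436 rose and 363 fell. After quantile normalization of the deposited values again 366 rose and 467 fell, so that 43.9% of the called genes rose in place of 54.6%.

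Further genes that rose were P2ry10 (1.03), Ankrd6 (0.83), Bcar3 (0.80, with probe sets that disagreed), Serpinb2 (0.74), Vsig4 (0.74), Slc30a4 (0.72), Ppm1l (0.71) and Mpp3 (0.70). Further genes that fell were Tifab (-0.79), Col8a1 (-0.70), Lxn (-0.62), Tm6sf1 (-0.61), Hddc3 (-0.56, with probe sets that disagreed), Tubb2a (-0.55), Acp5 (-0.53), Dglucy (-0.52) and Naip2 (-0.51). Emb, Tifab, Glrx, Tubb2a and Naip2, 5 of these 12 genes, lie on chromosome 13 in the assembly GRCm38.p6, as do 78 of the 356 genes that fell and could be placed on a chromosome. With the chromosome 13 median of each tumour as a covariate, 4 genes rose and 8 fell. That median itself went against the Cdkn2a level (r = -0.676), so calls can be lost through the variation the 2 share. The drop in the count therefore does not show that chromosome 13 accounts for the fit. The calls of Mpp3, Col8a1, Hddc3, Acp5 and Dglucy ended without the 7 tumours that stood apart. At the preset correlation mature B cell genes (adjusted p = 0.0077), MHC class II (0.0025), Myc targets (0.0014) and G2/M genes (0.025) were called upward, fibroblast (0.031) and adipocyte genes (0.025) downward, and each had adjusted p = 0.94 with an estimated correlation. The G2/M list turned downward without the 7 tumours (adjusted p = 0.41) and the calls of mature B cell genes (0.087), Myc targets (0.19), fibroblast (0.49) and adipocyte genes (0.28) ended, while S phase genes were called downward (0.0054) and immediate early genes upward (0.013). With other-cell scores as covariates the mature B cell (0.078) and adipocyte calls (0.078) ended and the fibroblast list turned upward (0.94). The fibroblast score was itself a covariate, so the end of its call was fixed in advance and its direction there carries no meaning. None of the members of the 6 lists called in all tumours passed over all genes. Adjusted over the list alone, the MHC class II genes H2-DMb2 (0.70), H2-Ob (0.61) and Ciita (0.44) rose, the adipocyte genes Pparg (-0.33), Lpl (-0.46) and Lep (-0.28) and the fibroblast gene Postn (-0.61) fell, and no mature B cell, Myc target or G2/M gene passed. The p53 target Polk (-0.25 ± 0.04, adjusted p = 0.002) fell and the macrophage gene Vsig4 rose, but neither list was called. Polk and Lep were chosen after their values were seen. In no called list of the 4 scores did the median, the mean and the test differ in sign. Among lists not called they differed for the sex-linked genes along the stage score, for mature B cell genes along the G2/M score, and along Cdkn2a for precursor B cell, plasma cell, T cell, macrophage, interferon, immediate early, p53 target, BCL2 family and lesion genes.

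**Figure D4:**
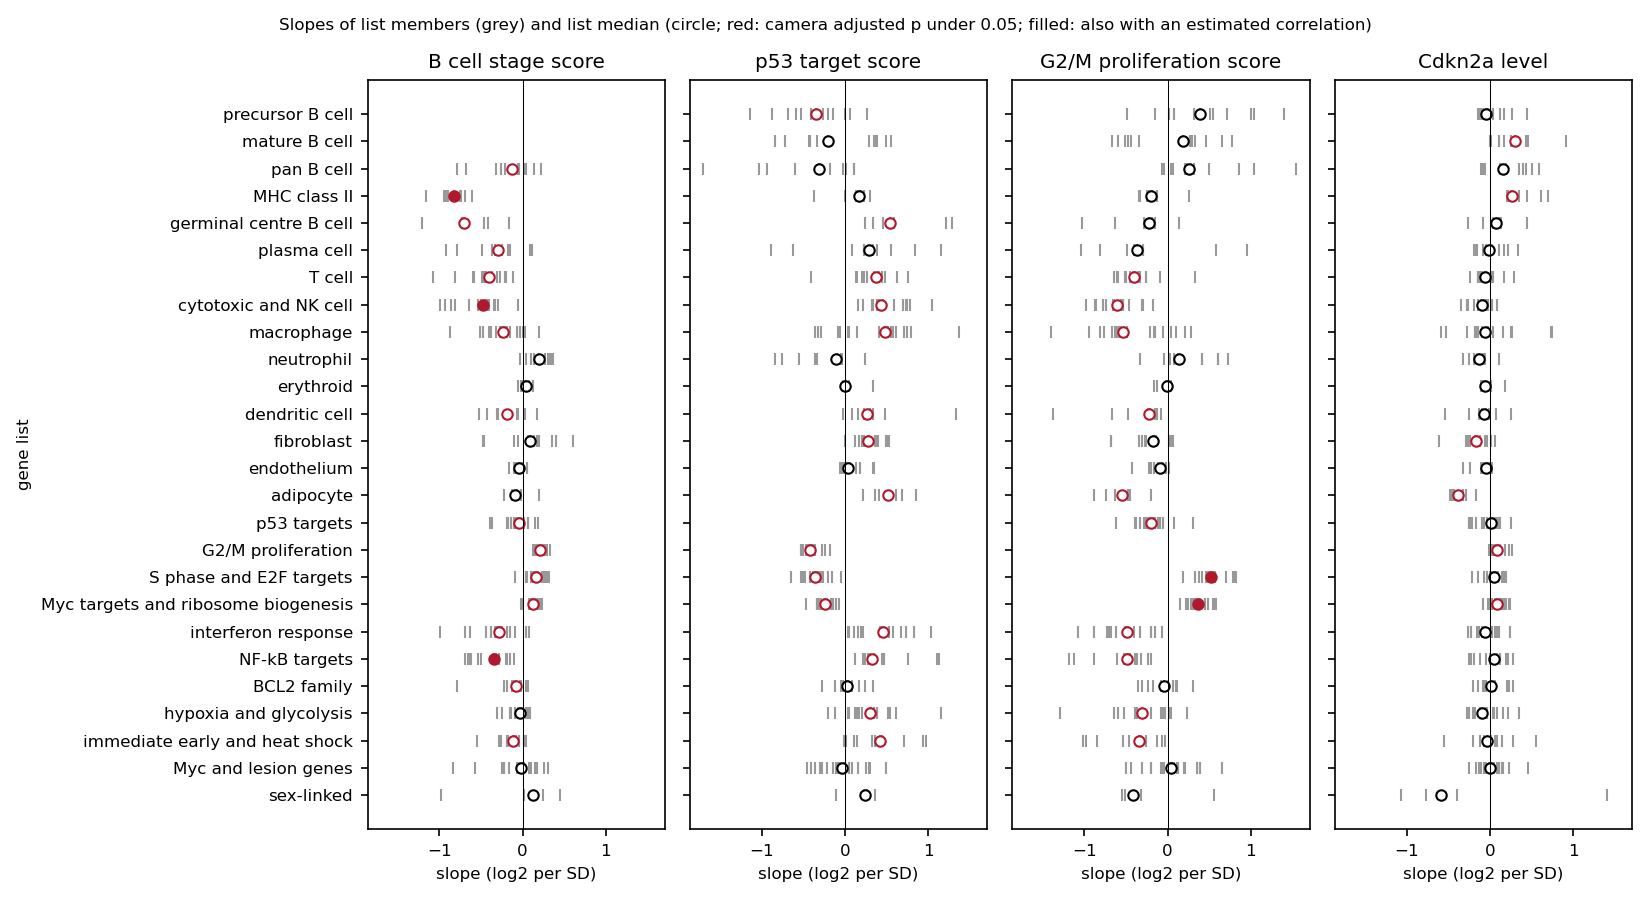
Slope of each list member (grey) and list median (circle) along 4 scores, in log2 per SD; red circles mark a camera adjusted p under 0.05, filled ones also with an estimated correlation. MHC class II, cytotoxic and NF-kB genes are filled along the stage score, S phase and Myc target genes along the G2/M score, and no list along the other scores.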

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

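Leaving out the 7 tumours that stood apart (a pan B cell score under -1 or a Myc level under 10) and adding the chromosome 13 median to the Cdkn2a fit were chosen after seeing the data. Of the main values under all alternatives 257 kept their direction and side of the threshold or stayed within the limit, 21 lost the threshold, 1 gained it, 2 reversed and 37 counts moved. Of the values of single genes and lists 3052 kept theirs, 436 lost the threshold, 32 gained it, 9 reversed and 3 moved. No change below has a tested cause, except that fewer genes or tumours enter some settings by construction, so for the rest the cause was not tested. No paired analysis was possible because the labels give 1 group. Dim genes near the background limit the smallest differences that the arrays show.

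With only genes above the median level, 747 genes had an SD of at least 1 and 3078 of at least 0.5. The r of mature B cell genes with NF-kB targets was 0.133 (adjusted p = 0.44) and of hypoxia with G2/M genes -0.333 (0.081), 332 genes fell along the stage score, 2008 rose along p53 targets and 2197 fell along G2/M. By the median absolute deviation the SD counts were 578 and 2746. With the mean of all probe sets, Myc with Mycn gave 0.0219 (adjusted p = 0.93). After median centring, mature B cell genes with NF-kB targets gave 0.348 (0.05) and 1086 genes rose along the stage score.

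Without the 3 arrays least like the others, mature B cell with plasma cell genes gave r = 0.289 (adjusted p = 0.12), Myc with Mycn 0.356 (0.059) and macrophage with interferon 0.343 (0.067). Along the stage score 215 genes rose and 294 fell, along p53 targets 1058 rose and 804 fell, and along G2/M 1992 fell.

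Without the 7 tumours 761 genes had an SD of at least 1. Precursor with mature B cell genes reversed to r = -0.517 (adjusted p = 0.0082), mature B cell genes with p53 targets reversed to 0.606 (0.0014), and precursor B cell genes with MHC class II came to -0.407 (0.041). Precursor B cell with G2/M genes fell short at 0.197 (0.34), Myc with S phase genes at 0.287 (0.16), Myc with Mycn at 0.245 (0.23), macrophage with interferon at 0.334 (0.097), macrophage with fibroblast at 0.236 (0.24) and G2/M with macrophage at -0.377 (0.06). Along p53 targets 894 genes rose and 408 fell, and Adgre1 (-0.18), Cidec (-0.059) and Lep (-0.028) reversed. Along G2/M 2373 rose and 1549 fell, and Adipoq (0.019), Lpl (0.083), Cidec (0.019) and Lep (0.016) reversed.

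Given the other-cell scores, 8 relations passed. Partial r was 0.208 (adjusted p = 0.37) for precursor B cell with G2/M genes, 0.0992 (0.72) for mature B cell with plasma cell genes, 0.274 (0.19) for mature B cell genes with NF-kB targets, -0.186 (0.39) for p53 targets with G2/M and 0.074 (0.74) for Myc with Mycn. It was 0.326 (0.12) for macrophage with interferon, -0.316 (0.16) for hypoxia with G2/M and -0.196 (0.37) for germinal centre with G2/M genes. With them as covariates 20 genes rose and 27 fell along the stage score, 125 and 38 along p53 targets, where Itgax (-0.062) and Pdgfra (-0.029) reversed, and 2120 and 2215 along G2/M.

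By Spearman correlation per gene 55 rose and 82 fell along the stage score, 1988 rose along p53 targets and 2139 fell along G2/M. At an adjusted p of 0.01, 114 rose and 226 fell along the stage score, and 89 and 53 along Cdkn2a. With the cluster of the score as a block 1985 rose and 1348 fell along G2/M. With the chromosome 13 median as a covariate 4 rose and 8 fell along Cdkn2a.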

Other observations

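The tests of Cdkn2a against the number of shifted chromosomes, of chromosome 13 among the genes that fell along Cdkn2a, of dilution and of chance pairing were chosen only after the result was seen. The labels put all tumours in 1 group, so no biological explanation that rests on a comparison of groups was tested for any pattern. In tumour 21, tumour 23 and tumour 28 Xist lay between 5.05 and 5.67 and Eif2s3y between 5.58 and 5.68, while the highest levels of the series were 13.54 for Xist and 10.51 for Eif2s3y. In tumour 27 they were at 10.16 and 10.13. The germinal centre gene Rgs13 was at 12.31 in tumour 18, 11.63 in tumour 27 and 10.50 in tumour 19. Ly6k was at 13.55 in tumour 32, 13.32 in tumour 19, 13.16 in tumour 26, 13.03 in tumour 5 and 12.38 in tumour 22, and Cd8b1 was highest in tumour 32 (13.33) and tumour 5 (13.21).

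Whole chromosomes moved in single tumours. With 6242 autosomal genes of mean level above 8 placed by the assembly GRCm38.p6, 78 of 741 combinations of chromosome and tumour had a median shift of at least 0.15 (log2) beyond 1000 random assignments of genes, 57 up and 21 down, in 25 tumours. Tumour 12 alone gave 14 of them, 7 up and 7 down, among them every fall of chromosomes 2, 7, 9 and 11. Each array was centred on its own median, so a shift is relative to the other chromosomes of that tumour. Chromosomes 3 and 15 were up in 10 tumours each, chromosome 5 in 7 and chromosome 14 in 5, and chromosome 13 was down in 7 (tumours 3, 10, 12, 15, 17, 24 and 25; lowest -0.63 in tumour 17).

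Of 75 shifts found from the genes at the lower positions of a chromosome, all (100%) lay on the same side in the other genes and 69 were past the limit there, in line with copy changes of whole chromosomes. Array quality as measured by the 3' to 5' difference and the hybridisation controls is argued against as the cause of most shifts. After regression on these 2 measures 71 of the 78 shifts (91.0%) stayed. The same holds for the T cell, macrophage, erythroid, fibroblast and pan B cell scores, since 66 (84.6%) stayed after regression on them. Array faults that these measures do not follow, and cells outside these scores, were not tested. Cdkn2a was higher in tumours with more shifted chromosomes (r = 0.489, permutation p = 0.00061, rho = 0.464, and r = 0.465 without tumours 9 and 14) and with a lower chromosome 13 median (r = -0.676, p = 1e-05, the smallest the permutations can give, rho = -0.606), adjusted p = 0.00061 and 2e-05 over 2 relations. Of 356 genes that fell along Cdkn2a 21.9% lie on chromosome 13, against 3.89% of 18032 genes tested, and of 433 that rose 20.3% lie on chromosome 5 and 19.6% on chromosome 3, so loss of chromosome 13 may set part of the genes that fell. DNA was not analysed here, and the relation with the number of shifted chromosomes was not recomputed without tumour 12 (14 shifts, Cdkn2a at 11.97).

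In tumours 5, 6, 8, 19, 23 and 26 the pan B cell score was low, with Pou2af1 between 3.10 and 6.81, but members were uneven: Btk fell by at most 0.42, and the fall of Cd72 was -1.60 in tumour 8 and -2.15 in tumour 23, where its level was above the median. Dilution by tissue with little Myc is argued against as the whole cause in 5 of the 6. There Myc fell by under 50% of the median fall of pan B cell genes, such as 0.053 against 2.56 in tumour 5. It is also argued against as the whole cause in tumour 8. In that tumour Myc fell by 1.34, and 4 of 12 pan B cell genes fell beyond that by over 2 SD. Among them Cd79a and Cd24a had whole falls of 5.34 and 4.37. As a part of the cause such dilution stays open, since Myc also fell by 1.05 and 1.12 in tumours 6 and 23. A hypothesis is that myeloid cells make up much of tumours 6, 8 and 23: all 3 were among the 4 highest scores of a second myeloid list written before the test (2.24, 2.25 and 2.25; next 2.02 in tumour 2), of 20 genes with 17 measured and 0 in an earlier list, with Tyrobp at 13.50, Fcer1g at 13.31 and Cybb at 12.97 in tumour 23, but Fgr (5.68) lay below its median of 6.54 and Ptafr (3.55) near its median of 3.62. A second is that plasmacytoid dendritic cells make up much of tumours 5, 19 and 26: all 3 were among the 4 highest scores of such a list (14 genes, 12 measured), behind tumour 32 (1.84), with Upb1 at 11.18 and Tex2 at 10.63 in tumour 5 against medians of 6.45 and 6.89, but Ly6d (12.07) was at 13.25 in tumour 1, Nucb2 (11.08) was at 11.47 in tumour 21, and Tlr9 (6.00) and Klk1 (7.76) lay near their medians of 6.04 and 7.75. Upb1 (11.27 and 10.11) and Tex2 (10.27 and 9.70) were also high in tumours 19 and 26. Tlr7, however, was at its median of 6.15 in tumour 19 and at 6.05 in tumour 26. Rpgrip1 was at 8.12 in tumour 19, below its median of 10.54. Tumours 6, 8 and 23 already stood out by Itgam and Adgre1, and tumours 5 and 19 by Siglech. Over the whole macrophage list, however, tumour 8 (0.68) scored below tumours 22 (0.87) and 1 (0.76). Neutrophil scores were negative in tumours 6, 8 and 23 (-0.40, -1.70 and -1.01). Genes of 1 cell type tend to move together, so the ranks on both second lists were largely set beforehand. They lend the hypotheses no independent weight. Tumour 2, with a myeloid score of 2.02, had a pan B cell score of 0.27, so a high score alone does not show such a share. In tumours 5, 19 and 26 the G2/M scores (-0.014, -0.078 and -0.019) and Myc target scores (-0.017, -0.074 and 0.005) lay near the series mean. That mean is pulled down by tumours such as 2, 6 and 8 (G2/M scores -2.46, -1.51 and -1.45), and most tumours scored higher than these 3. The values argue against non-dividing cells with little Myc as most of tumours 5, 19 and 26, but a smaller share of such cells stays open. Whether other cells that divide and hold Myc or lymphoma cells that express such genes are present there stays open. In tumours 6, 8 and 23 other cells and such lymphoma cells both stay open.

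Bpifa2 was above 12 in 9 tumours (3, 7, 8, 13, 15, 25, 37, 38 and 39). Salivary gland tissue carried with the tumour was tested with 15 salivary epithelial genes, and 5 of the 9 were among the 9 highest scores (2.08 by chance), led by tumour 25 (1.92) and tumour 7 (1.34). The bounds set before the test were at least 8 for and at most 4 against, so salivary tissue as a possible explanation stays open.

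For each of the 4 scores only the real 1 of 100 pairings of the score with the tumours called as many genes. The scores come from genes of the same arrays, and other genes that move with their members favour the real pairing. That outcome was therefore largely set beforehand, and no conclusion is drawn from it. The real and highest other counts were 1080 and 374 along the stage score, 6103 and 304 along p53 targets, 7362 and 3430 along G2/M, and 799 and 0 along Cdkn2a.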
